A study of Mus musculus with 6 samples.

How the data were processed

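Tumour miRNA was profiled on 6 one-colour Agilent miRNA arrays, 1 per mouse, with 3 GLE-treated and 3 saline-treated (model) mice per the labels. The labels number the replicates 1 to 3 in each group, state that each sample is a separate tumour-bearing mouse, and give TRIzol extraction and a quality check of the RNA. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction (version 10.7.1.1, also named in the submitters' processing notes), which subtracted background and a spatial trend from each spot. Their values are intensity on a linear scale, not normalised between arrays, per the file headers and the values themselves, which reach below 0. Each file holds 56430 spots that are not controls, for 4415 probes and 1881 miRNAs, and 0 of them were saturated. Feature Extraction also gives a total per probe and per miRNA and flags for detection and outliers. The authors also deposited processed values for each miRNA and array, whose making is not given in the sources used here. By comparison with the arrays, the deposited table is on a log2 scale: its ranks followed the summed probe totals of the same array (Spearman correlation across miRNAs 0.998 to 0.999), with a slope of 1.00 to 1.11 on their log2 values. Among its 300 brightest values, those of equal rank had a median range over arrays of 0, against 0.73 for the probe totals, as quantile normalisation leaves them. Its column medians were −3.20, −3.32 and −3.27 for GLE replicates 1 to 3 and −3.32, −3.17 and −3.13 for model replicates 1 to 3. Each median equals the column's lowest value, which 69.2% to 75.8% of its miRNAs share. The columns hold single arrays, so no direction or centring between groups applies. It served as an alternative only. Probe positions are those in the files, on mm9 per the file headers; the gene annotation at hand was of another build, so no position was set against it.

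The main values were computed from the processed signal in R 4.3.3 with limma 3.58.1. Control spots and spots flagged as outliers (1401 to 1883 per array) were left out, and the spots of a probe were averaged. A probe counted as detected on an array when more than a share of 0.5 of its used spots were well above background. Each array was divided by its 75th percentile over the 636 probes detected on all 6 arrays, values were then floored at −4.25 (log2, the median over arrays of the lowest scaled signal among detected probes), and log2 was taken. A miRNA's value was the mean over its probes detected on all arrays of at least 1 group. This left 388 miRNAs for testing. The other 1493 were not tested, of which 1383 were detected on no array. Of the 294 tested miRNAs with more than 1 probe used, 31 had probes whose differences had opposite signs, and 0 had probes that differed by over 0.5. No spot values were shared between arrays (0% identical). For a miRNA not well above background on any array of a group, the fold given compares group means of normalised log2 values. Each array of that group takes the higher of the lowest detected signal and the probe's own value. This fold leaves out the spread between arrays and is not a lower bound.

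Groups were compared with limma's lmFit and eBayes (two-sided, 4 residual and 3.05 prior degrees of freedom), with Benjamini-Hochberg adjustment over all tested miRNAs and a threshold of 0.05. The 17 miRNA lists, the rule for named miRNAs and the main design were fixed before the data were examined. The lists cover hepatocyte, immune, erythrocyte, muscle, endothelial, fibroblast and smooth muscle, and epithelial and skin miRNAs, the let-7, miR-30 and miR-23, miR-24 and miR-27 families, the miR-17-92, Dlk1-Dio3, Sfmbt2 and miR-290 to miR-295 clusters, miRNAs raised in hepatocellular carcinoma, p53 and growth-restraining miRNAs, and entries that match rRNA or tRNA fragments. They held 106 tested miRNAs, of which miR-155-5p and miR-18a-5p stand in 2 lists each. The 15 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list moves one way on balance and does not compare it with other miRNAs. Single values per array were compared with two-sided exact permutation tests over all 20 relabelings, whose smallest p is 0.1, and relations across arrays with exact permutation over all 720 pairings. Named miRNAs are those past the threshold (there were 0) with, in their place, the 6 of smallest p in each direction, 29 anchors of the lists whatever they showed, of which 25 were tested, and up to 4 members of largest moderated statistic from each list that passed. Together these are 50 miRNAs, of which 46 were tested. Any other miRNA is marked where it is named as chosen after its values were seen.

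The test was tried on simulated data with the means and spreads of the 388 miRNAs before use. Over 20 data sets, 4.66% of calls were false, 0 of 20 data sets with no difference had a call, and the immune list, shifted by 0.6, was called in 20 of 20. These simulations drew miRNAs independently and used the preset correlation for the list. The list tests with an estimated correlation and with fry were not tried on a shifted list, so their power is not known. In a further 100 data sets with no difference and the correlation of these arrays, 6 had any miRNA past the threshold. The list test with the preset correlation called any list in 92 of them and at least 4 lists in 53, against 0 with an estimated correlation and 5 with fry. In these 100 data sets every miRNA was a combination of the same 4 patterns of deviation found in the arrays, with no further noise of its own. Correlations taken from so few arrays are imprecise, so these rates depend on that setting.

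The alternatives tried were other scalings between arrays (percentile over all probes, quantile normalisation, none), normexp background correction with an offset of 50, the total per miRNA of Feature Extraction, the deposited table of log2 values, the brightest probe, other filters on dim probes, a lower floor, eBayes with trend or robust, the replicate number as a block, a combined rule of unadjusted p and 2-fold change, and leaving out each array in turn. Scaling by the labelling spike-ins and the sum of probe totals were added after seeing the data. Slide and scan blocks were not run, since all arrays share 1 slide and 1 scan. Labelling spike-ins, added before labelling, varied 1.17-fold and 1.18-fold over the arrays. Hybridisation spike-ins varied 3.52-fold and 3.42-fold. Over the alternatives the median difference of all tested miRNAs stayed between −0.080 and 0.079.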

Results

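MicroRNA levels were measured in tumours of C57BL/6 mice that had been inoculated in the right flank with Hepa1-6 cells, a mouse hepatoma line. Per the labels, 3 mice received a treatment called GLE, which the labels do not spell out, at a total of 0.023 g per day for a mouse of 10 g. The other 3 mice, called the model group, received 0.2 ml of saline daily for 28 days. Each tumour's total RNA was labelled with Cy3 and hybridised to its own array, so every group held 3 separate mice. The arrays carried probes for 1881 mouse miRNAs. Between 378 and 458 miRNAs were detected per array, with a mean of 428 ± 30.2 (SD, n = 3) in GLE tumours and 408 ± 43.8 (SD, n = 3) in model tumours. That difference was within the spread of the arrays (two-sided exact permutation p = 0.6, where the smallest possible value was 0.1). The 75th percentile signal of the probes detected on all 6 arrays ran from 203 to 364 intensity units, and its group means also differed by less than the spread (exact permutation p = 0.7). A total of 388 miRNAs were bright enough to be tested. The number of arrays limits the precision: the median 95% interval of a difference was ± 0.54 on the log2 scale.

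The design named 1 comparison, tumours of GLE-treated mice against those of the model group, which received saline. Differences below are GLE minus model on the log2 scale, ± SE of the limma fit over 3 arrays per group. No single miRNA passed the threshold. As groups, the miRNAs of immune cells lay higher in GLE tumours by a mean of 0.60, those of fibroblasts and smooth muscle by 0.54, and those of the p53 and growth-restraining list by 0.27, while the miR-17-92 clusters lay lower by a mean difference of −0.23. These 4 of the 15 tested lists passed limma's camera test with a preset correlation. None of the 15 passed with a correlation estimated from these arrays (smallest adjusted p = 0.686 with an estimated correlation) or with fry (smallest adjusted p = 0.289). The preset test was also run on 100 simulated data sets with no difference and with the correlation between miRNAs found on these arrays. It called at least 1 list in 92 of them and at least 4 lists in 53, so the 4 calls have to be read with these rates.

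The 10 immune cell miRNAs were all measurable, and 9 of them had a positive difference (median 0.67). Among the 9, miR-181a-5p was level at 0.017 ± 0.16, and the negative member was miR-181b-5p at −0.15 ± 0.16. These miR-181 members were named after their values were seen. The adjusted p of the list was 0.000742 in limma's camera test, and it was 0.729 with an estimated correlation. miR-342-3p, a miRNA of haematopoietic cells, had the largest difference of all 388 tested miRNAs at 1.21 ± 0.51, a 2.31-fold higher level with a 95% interval of 1.00 to 5.31. miR-150-5p, which marks mature lymphocytes (probe at chromosome 7, 52377140 to 52377153, mm9), differed by 0.85 ± 0.41, and miR-155-5p, which is induced in activated lymphocytes and macrophages (chromosome 16, 84714395 to 84714410), by 0.71 ± 0.35. The value of miR-146a-5p, a feedback regulator of inflammatory signalling (chromosome 11, 43187908 to 43187925), was 0.63 ± 0.24. miR-223-3p of neutrophils and other myeloid cells differed by 0.84 ± 0.49, and miR-142a-3p, present across blood cell lineages, by 0.53 ± 0.27. In GLE replicate 2, miR-342-3p, miR-150-5p, miR-155-5p, miR-223-3p and miR-142a-3p lay within the range of the model tumours, and miR-146a-5p lay above it. None of these passed over all tested miRNAs, and 0 of the 10 passed when adjusted over the list alone (smallest adjusted p = 0.160, limma). The list mean was −0.81, −1.48 and −0.35 in GLE replicates 1, 2 and 3 and −1.55, −1.69 and −1.21 in model replicates 1, 2 and 3 (exact permutation p = 0.2). Without GLE replicate 3, the shift was 0.34, with an adjusted p of 0.00375 in the camera test and an exact permutation p of 0.4 for the list mean (smallest possible 0.1).

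The fibroblast and smooth muscle list followed, with 5 of its 6 tested members at a positive difference and a mean of 0.54 (camera adjusted p = 0.0277, and adjusted p = 0.729 with an estimated correlation). The values of this list ran together with the immune list over the 6 arrays (Pearson r = 0.98, exact permutation p = 0.00278, adjusted p = 0.0278 over 10 relations computed; Spearman rho = 0.94, exact permutation p = 0.0167, adjusted p = 0.167; r = 0.91 without the 2 arrays farthest from the median). Its leading members belong to the miR-199 and miR-214 group of mesenchymal cells. miR-199b-5p differed by 0.93 ± 0.61, miR-199a-3p by 0.81 ± 0.44, miR-199a-5p by 0.68 ± 0.44 and miR-214-3p by 0.61 ± 0.39. The smooth muscle pair was flatter, with miR-143-3p at 0.27 ± 0.21 and miR-145a-5p at −0.026 ± 0.20, the latter changing sign under 3 alternatives that keep every array. In the endothelial list only miR-126a-3p, which lies within the endothelial gene Egfl7 (probe at chromosome 2, 26591407 to 26591423, mm9), was tested. It differed by 0.49 ± 0.19, a 1.41-fold higher level, and its 3 GLE values lay above its 3 model values. Adjusted over the list alone, a list of 1 tested member, its p stayed at 0.0346 (limma), and over all tested miRNAs the adjusted p was 0.935. The fibroblast list lost its call without GLE replicate 3 (shift 0.19, adjusted p = 0.315), without model replicate 1 (0.54, adjusted p = 0.05003) and without model replicate 2 (0.42, adjusted p = 0.0658). Its shift was 0.90 without GLE replicate 2.

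**Figure D1:**
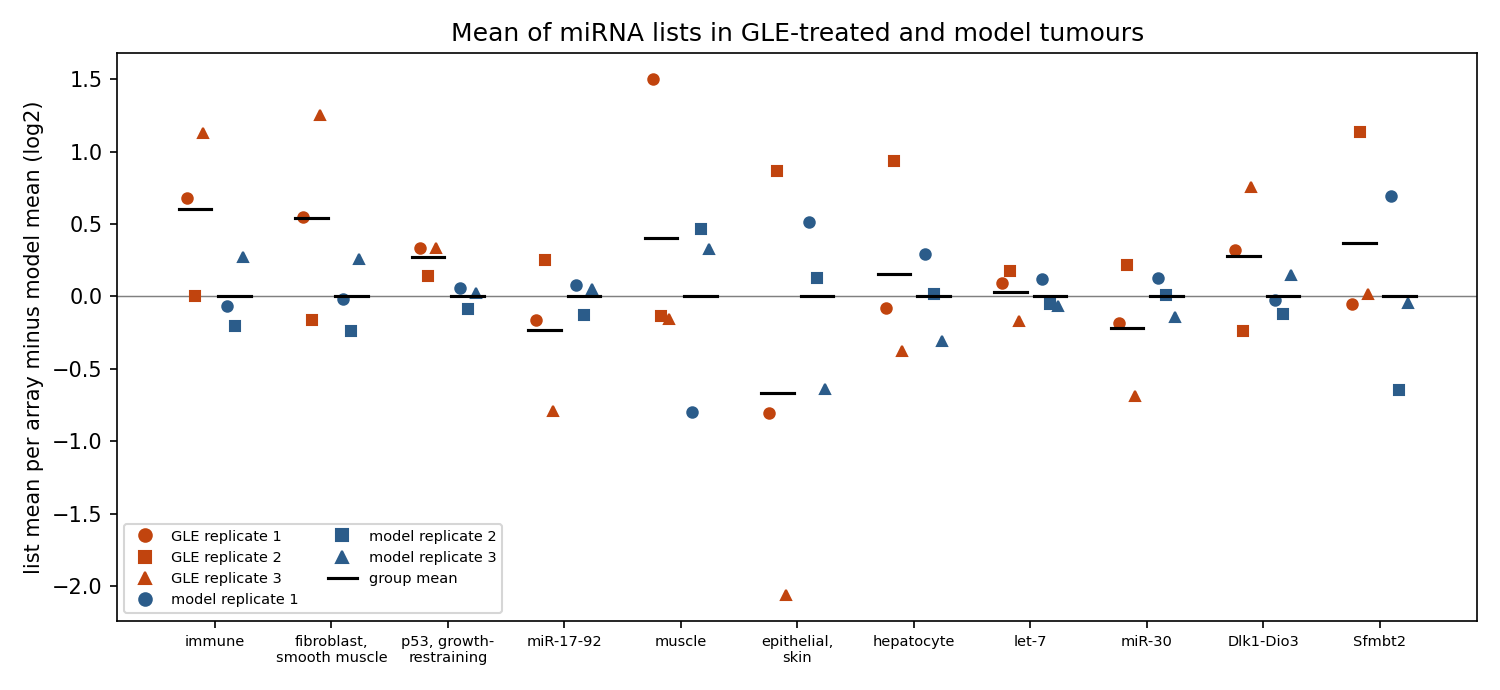
Mean of each miRNA list per array on the log2 scale, minus the model mean of that list, for 11 of the lists. Each point is 1 tumour, marked by group and replicate number, and black lines are group means over 3 arrays. GLE replicates 1 and 3 lie above the model mean in the immune and fibroblast lists, while GLE replicate 2 lies among the model tumours.

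The miR-17-92 cluster and its paralogues, which are induced by MYC and promote proliferation, had negative differences in all 10 tested members, with a mean of −0.23 (camera adjusted p = 0.0179, and adjusted p = 0.729 with an estimated correlation). miR-106b-5p and miR-93-5p, whose probes map near each other on chromosome 5 (138606981 to 138606996 and 138606774 to 138606787, mm9), both differed by −0.35, with SEs of 0.35 and 0.31. miR-17-5p differed by −0.35 ± 0.28, miR-19b-3p by −0.24 ± 0.27 and miR-92a-3p by −0.17 ± 0.23. The listed probes of the last 3 also map to the paralogous cluster on chromosome X, so the arrays do not separate the copies. Adjusted over the list alone, 0 members passed (smallest adjusted p = 0.590, limma). The list's sign rested on 1 tumour: without GLE replicate 3 the shift was 0.045 (adjusted p = 0.749). It was −0.48 without GLE replicate 2 and −0.19 without model replicate 1, where the call was lost (adjusted p = 0.0899).

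In the list of p53-induced and growth-restraining miRNAs, 8 of 10 tested members had a positive difference (mean 0.27, camera adjusted p = 0.0179, and adjusted p = 0.686 with an estimated correlation). Its leading members were not the p53-induced ones except miR-34b-5p. miR-195a-5p at 0.64 ± 0.31 and miR-497a-5p at 0.59 ± 0.30 share the seed of the miR-15 family, which targets cell cycle regulators, and their probes map to neighbouring positions on chromosome 11 (70048567 to 70048584 and 70048235 to 70048253, mm9). In GLE replicate 2 both stood at −1.25, within the range of the model tumours. miR-15a-5p differed by 0.36 ± 0.18 and miR-16-5p by 0.28 ± 0.16. miR-34a-5p, a direct transcriptional target of p53, differed by 0.25 ± 0.19, and miR-29a-3p by 0.17 ± 0.16. miR-34b-5p was well above background on 3 GLE arrays and on 0 model arrays. The fold between its group means, GLE over model, was 1.55. For each model array the higher of the probe's own value and the lowest signal among detected probes was taken. This fold is not a lower bound: the interval of the limma fit ran from 0.91-fold to 2.84-fold (limma adjusted p = 0.935). The value of miR-34b-5p in GLE replicate 2 was at the floor of −4.25, as on 2 model arrays. Without GLE replicate 3 the fold between group means was 1.20. Without this miRNA the remaining 9 members had a mean of 0.22 and a median of 0.25. Of the 10 members 0 passed when adjusted over the list alone (smallest adjusted p = 0.228, limma). It was the one tested list whose per-array means did not overlap between the groups, at 1.01, 0.81 and 1.01 in GLE replicates 1, 2 and 3 against 0.73, 0.59 and 0.70 in model replicates 1, 2 and 3, the smallest exact permutation p possible (0.1). By chance, 10% of lists would do so with 3 against 3 arrays, and 15 lists were tested, so 1 such list is no more than chance gives. The call of the p53 list was lost without GLE replicate 2 (shift 0.33, adjusted p = 0.196), an omission that widened the shift.

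Liver-type miRNAs did not differ as a group. The hepatocyte list had a mean difference of 0.16 with 3 of 6 tested members positive (camera adjusted p = 0.926, 0 members past when adjusted over the list alone). With an array left out, its mean ran from −0.23 (without GLE replicate 2) to 0.43, and 0 of these fits passed the camera test. miR-122-5p, the abundant miRNA of differentiated hepatocytes, was detected on 1 GLE and 1 model array and was not tested. miR-192-5p differed by 0.54 ± 1.00, with one tumour, GLE replicate 2, at 0.26 against −3.01 and −3.46 in the other GLE tumours, and without that tumour the difference was −0.62. miR-148a-3p differed by −0.083 ± 0.30. Among miRNAs commonly raised in hepatocellular carcinoma, 5 of 7 tested members were positive (mean 0.25, camera adjusted p = 0.101, 0 past when adjusted over the list alone). miR-21a-5p, a growth-promoting miRNA, differed by 0.39 ± 0.18. Of the summed signal of the 636 probes detected on all 6 arrays, it took 9.05% ± 1.22 in GLE tumours and 6.99% ± 0.515 in model tumours (SD, n = 3). miR-221-3p differed by 0.040 ± 0.16 and changed sign under several scalings. The hypoxia-induced miR-210-3p differed by −0.25 ± 0.20, and miR-224-5p was detected on 0 arrays.

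The let-7 family, a brake on growth that LIN28 controls, was near level. Its 9 tested members had a mean of 0.034 with 5 positive (camera adjusted p = 0.756), and let-7a-5p differed by 0.020 ± 0.18. The family's sign turned under 3 of the scalings tried, namely the percentile over all probes (−0.054), quantile normalisation and the labelling spike-ins. The miR-30 family had 1 positive member of 5 (mean −0.22, camera adjusted p = 0.101), with miR-30a-5p at −0.40 ± 0.35, and its mean was 0.016 without GLE replicate 3 and −0.44 without GLE replicate 2 (adjusted p = 0.0116). The miR-23, miR-24 and miR-27 clusters were at −0.062 with 1 of 5 positive (camera adjusted p = 0.373), a mean that was 0.013 without scaling. In each of these 3 lists, 0 members passed when adjusted over the list alone.

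Muscle, epithelial and erythrocyte miRNAs, listed for tissue that a flank tumour piece can contain, differed between groups by less than their SD over GLE tumours. Which cells their signal came from was not tested, and the tumour cells themselves may be among them. The muscle list had a mean of 0.40 with 3 of 4 positive (camera adjusted p = 0.345). miR-1a-3p differed by 0.62 ± 0.59, miR-133a-3p by 0.52 ± 0.56 and miR-206-3p by −0.019 ± 0.41 (0.056 with no scaling between arrays), and the list mean was −0.14 without GLE replicate 1 and 0.69 without GLE replicate 3 (adjusted p = 0.0471). Of the epithelial and skin list, 0 of 3 tested members were positive (mean −0.67, camera adjusted p = 0.101), and the mean was 0.032 without GLE replicate 3, while the list passed without GLE replicate 2 (−1.43, adjusted p = 0.00374) and without model replicate 3 (−0.99, adjusted p = 0.0466). miR-200c-3p was detected on 0 arrays and the keratinocyte miRNA miR-205-5p on 1 model array. The erythrocyte miRNA miR-451a differed by −0.26 ± 0.56, and with 2 tested members the erythrocyte list was not tested as a group. Among genomic clusters, the imprinted Dlk1-Dio3 cluster on chromosome 12 was at 0.28 with 9 of 12 positive (camera adjusted p = 0.101), and its miR-127-3p differed by 0.57 ± 0.40. The cluster was at 0.042 without GLE replicate 3 and at 0.54 without GLE replicate 2 (adjusted p = 0.0236). The rodent Sfmbt2 cluster, whose near-identical members can cross-hybridise, was at 0.37 with 10 of 10 positive (camera adjusted p = 0.0732), and at −0.019 without GLE replicate 2, while it passed without GLE replicate 1 (0.58, adjusted p = 0.000233), GLE replicate 3 (0.54, adjusted p = 0.00127) or model replicate 1 (0.71, adjusted p = 1.41e-05). The cluster of miR-290 to miR-295 of pluripotent cells was at 0.18 with 4 of 5 positive (camera adjusted p = 0.373), at 0.020 without GLE replicate 3 and at 0.46 without GLE replicate 2. Database entries that match rRNA or tRNA fragments, a sign of RNA quality, were at −0.15 with 0 of 3 positive (camera adjusted p = 0.211), and at −0.063 without GLE replicate 2. In none of the lists of this paragraph did a member pass when adjusted over the list alone.

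Over single miRNAs, 0 of 388 passed limma's test after Benjamini-Hochberg adjustment (smallest adjusted p = 0.935), and 6 had an unadjusted p under 0.05, where chance alone gives 19.4. All 6 were higher in GLE tumours. Besides miR-342-3p, miR-146a-5p and miR-126a-3p, they were miR-7a-5p, which restrains growth factor signalling, at 0.60 ± 0.21, miR-378a-5p, which lies within the metabolic coactivator gene Ppargc1b, at 0.56 ± 0.22, and miR-340-5p at 0.43 ± 0.18. On the lower side, the smallest p belonged to miR-31-3p at −0.72 ± 0.34 (unadjusted p = 0.0674), followed by miR-6969-5p at −0.55 ± 0.28, miR-193a-3p at −0.33 ± 0.18, miR-139-3p at −0.27 ± 0.16, miR-711 at −0.45 ± 0.27 and miR-149-5p at −0.30 ± 0.19. Single arrays carried much of several of these values: without GLE replicate 3, miR-342-3p was at 0.76, miR-31-3p at −0.37, miR-193a-3p at −0.21 and miR-149-5p at −0.15, and without model replicate 2, miR-6969-5p was at −0.34 and miR-711 at −0.19. In 26 miRNAs, or 6.70%, the groups did not overlap, against 10% by chance for 3 against 3. The middle 95% of differences ran from −0.43 to 0.70 around a median of 0.0078. In simulated data of the same size, the same test called 40.1% of miRNAs changed 1.5-fold, 69.3% of those changed 2-fold and 95% of those changed 4-fold, so many changes of up to 2-fold would go uncalled at this number of arrays. Each simulated data set held 40 changed miRNAs at each of these folds and drew miRNAs independently. With fewer true changes the adjustment is stricter, so the share called in these data may be lower. Without GLE replicate 2, 2 miRNAs passed and 107 had an unadjusted p under 0.05. The 2 were miR-342-3p (1.79, adjusted p = 0.0467) and miR-338-3p (adjusted p = 0.0409), the latter named here after its values were seen. For miR-338-3p no size is given, since it was detected on 1 model array and its model values were at or next to the floor (−4.23, −4.25 and −4.25), which leaves almost no spread in that group.

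**Figure D2:**
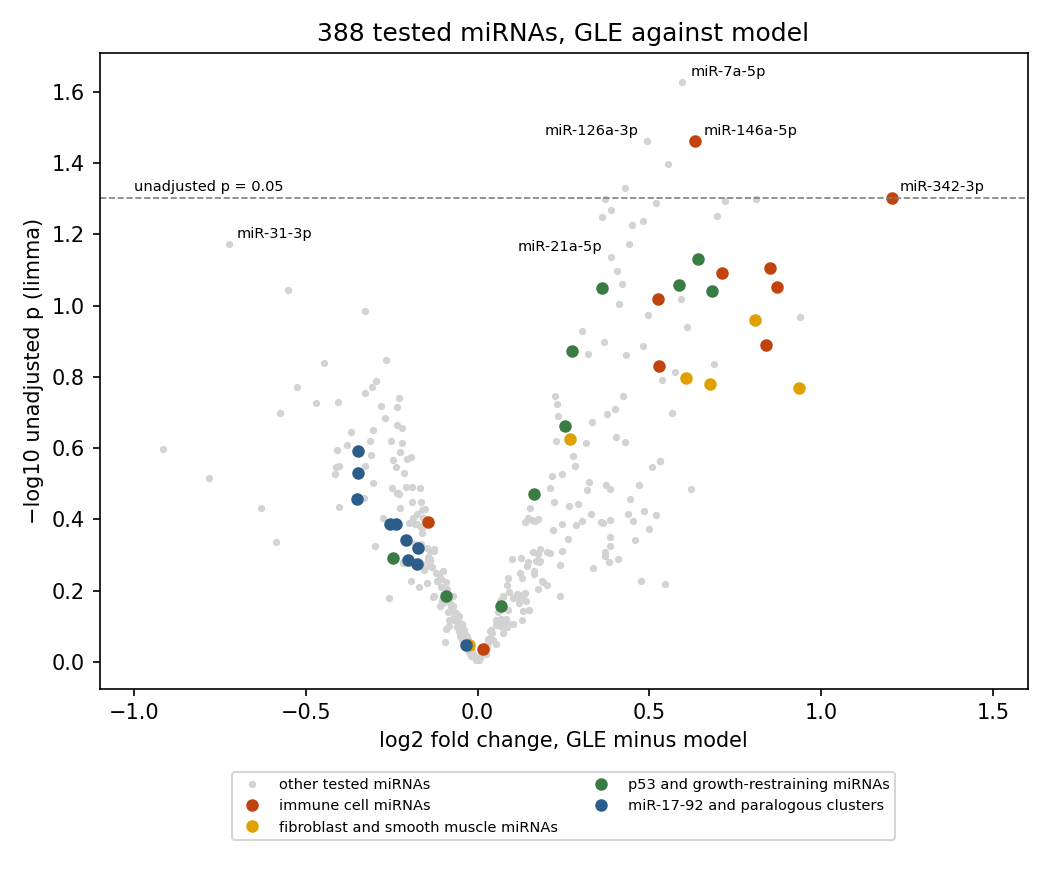
Difference between GLE and model tumours on the log2 scale (x axis) against −log10 of the unadjusted limma p (y axis) for the 388 tested miRNAs. Each point is 1 miRNA, coloured where it belongs to a list that passed the camera test with the preset correlation, and the 6 miRNAs above the dashed line all lie on the side higher in GLE.

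**Figure D3:**
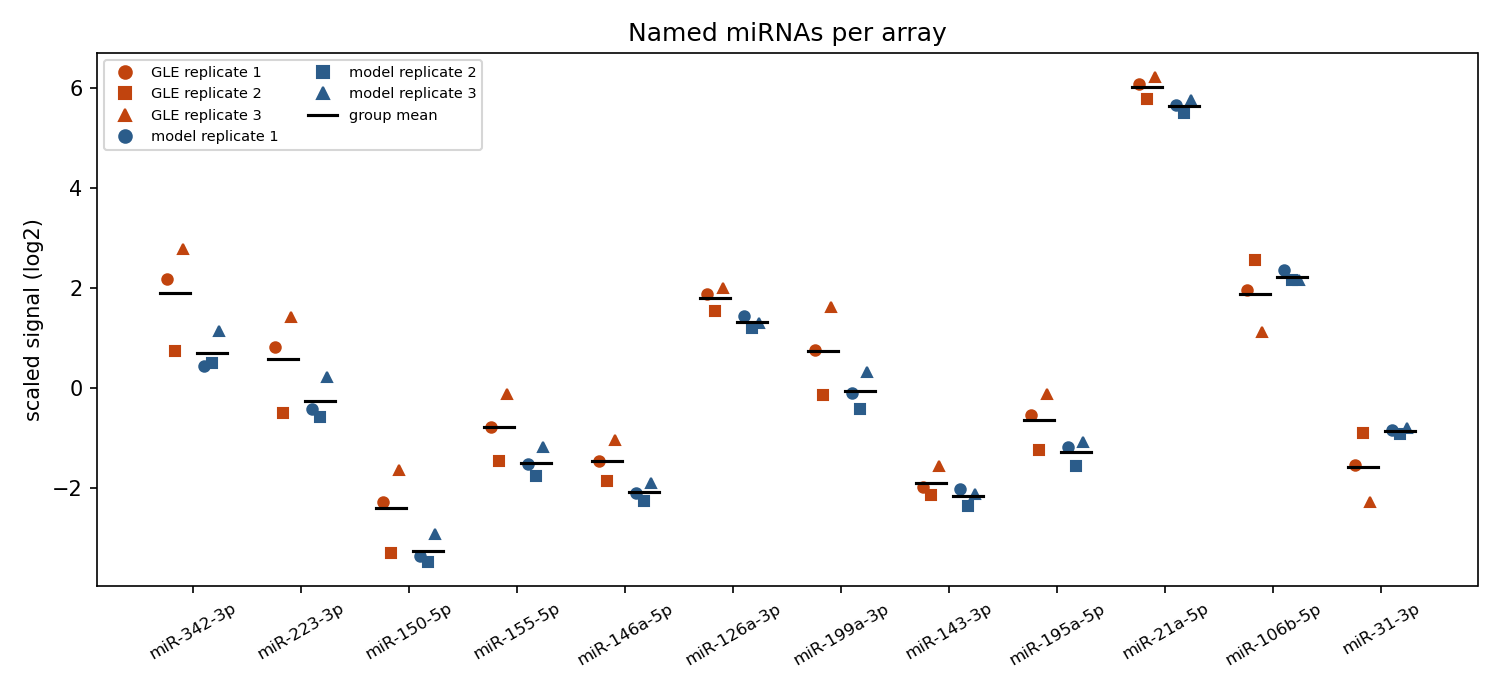
Scaled signal of 12 named miRNAs on the log2 scale in each of the 6 tumours, with replicate number given by marker shape and group means as black lines. In miR-342-3p, GLE replicates 1 and 3 stand at 2.17 and 2.78, GLE replicate 2 at 0.73, and the model tumours at 0.43, 0.49 and 1.14.

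The GLE tumours differed among themselves more than the model tumours did. The SD over GLE arrays was larger than that over model arrays for 297 of the 388 miRNAs (76.5%), with median SDs of 0.33 and 0.17. Correlations across miRNAs between pairs of GLE arrays ran from 0.913 to 0.974, between pairs of model arrays from 0.981 to 0.982, and between the groups from 0.937 to 0.992; miRNAs are not independent replicates. Shares were taken of the summed signal of the probes detected on all 6 arrays. The brightest miRNA, miR-6366, with 35.7% ± 2.45 in GLE and 38.1% ± 2.44 in model tumours, and miR-3963, another bright one, with 8.99% ± 1.20 and 9.64% ± 1.82 (SD, n = 3), differed by less than their spread. Both were named for their brightness, after their values were seen. All 6 arrays lay on 1 slide and were scanned together, so no slide or scan batch could be compared. The GLE arrays filled row 1 of that slide and the model arrays row 2, so slide row and group cannot be told apart.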

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

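The tests in this part were chosen after the values were seen, except the limma test on the total per miRNA, which was planned. Among the 1493 miRNAs left out of the comparison, 110 were detected on at least 1 array. Of these, 2 were seen on at least 2 GLE arrays and on 0 model arrays, and 1 the other way round, so the imbalance is small. miR-342-5p, the other arm of the precursor of miR-342-3p, was detected on 2 GLE arrays, at −3.35 in replicate 1 and −2.74 in replicate 3, with the remaining 4 arrays at the floor of −4.25. miR-34c-5p, which is transcribed together with miR-34b, was also detected on 2 GLE arrays and on 0 model arrays, at −3.85 in replicate 1 and −2.96 in replicate 3. The miRNA seen the other way round was miR-421-3p, detected on 2 model arrays. These 3 were named after their values were seen, and none was tested.

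The total per miRNA that Feature Extraction gives would have made miR-342-5p a strong call, with a difference of 8.14 (adjusted p = 0.00226, limma), the 1 miRNA past the threshold under that column. On GLE replicate 3 its total was 955 intensity units although its own probe totals summed to 5.32, and the total of miR-342-3p on that array was 951. Such totals, over 2 times the sum of the probe totals, made up 606 of 3080 detected totals (19.7%). Of them 98.5% lay, within 0.5 units, between the total of the detected miRNA listed before and that total plus their own probe totals, against 5.28% for the miRNA listed after and 6.97% for random donors, so a carried-over total may account for nearly all of them. No biological explanation was tested for this pattern, and the main values, taken from single spots, do not use these totals.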

How the results depend on the processing

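All alternatives were planned except scaling by labelling spike-ins and the sum of probe totals, which were chosen after seeing the data. With 16 other fits and 6 left-out arrays, 0 miRNAs passed in all but 2: the Feature Extraction total per miRNA called 1 (miR-342-5p, whose total may be carried over) and leaving out GLE replicate 2 called 2 (range 0 to 2 over the left-out arrays). Unadjusted p under 0.05 with a 2-fold change named 1, miR-342-3p. Counts at unadjusted p under 0.05, 6 in the main fit, ran from 5 to 18, and from 0 to 107 with an array left out, the 107 without GLE replicate 2.

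The 4 lists past the threshold became 7 with normexp, 1 with the total per miRNA, 0 with an estimated correlation and 0 with fry, and 3 to 6 with an array left out. With both of those set tests the shifts stay by construction at 0.60 (immune), 0.54 (fibroblast), −0.23 (miR-17-92) and 0.27 (p53), and the adjusted p was 0.729, 0.729, 0.729 and 0.686 with an estimated correlation and 0.757, 0.757, 0.757 and 0.289 with fry. The immune list kept its call in the other 22 alternatives. With the total per miRNA the fibroblast (0.45), miR-17-92 (−0.33) and p53 (0.32) lists lost theirs (adjusted p = 0.108 each). The miR-17-92 list lost its call with quantile normalisation (−0.28, adjusted p = 0.0701) and with no filter on dim probes (−0.19, adjusted p = 0.691), and the fibroblast list with probes detected on at least 1 array (0.54, adjusted p = 0.0847). The cause of these was not tested. Adjusted p ranged over all alternatives from 3.71e-12 to 0.757 for the immune list, 0.000430 to 0.757 for the fibroblast list, 0.000118 to 0.757 for the miR-17-92 list and 1.18e-13 to 0.686 for the p53 list. The lowest immune value came from the camera test with no filter on dim probes. That setting compares the list with all 1881 miRNAs, of which 1383 were detected on no array.

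With an array left out, the immune shift ran from 0.34 to 0.90 and the fibroblast shift from 0.19 to 0.90 (past the threshold in 3 of 6). The miR-17-92 shift ran from −0.48 to 0.045, reversed without GLE replicate 3, and that of p53 from 0.23 to 0.33. With all arrays kept, the shift ran from 0.39 (normexp) to 0.68 (no scaling) for immune, 0.32 (normexp) to 0.62 (no scaling) for fibroblast, −0.33 (total per miRNA, where totals may be carried over) to −0.16 (no scaling) for miR-17-92 and 0.17 (normexp) to 0.61 (deposited table) for p53 miRNAs. The difference in detected miRNAs, 20.3, ran from 5.5 to 45.5. That in overall signal, 0.075 (log2), ran from −0.16 to 0.26, reversed without GLE replicate 2 (−0.16) and without model replicate 3 (−0.042). With the replicate number as a block, 0 miRNAs and 6 lists passed and 17 miRNAs had an unadjusted p under 0.05. Same-numbered arrays shared a slide column (1, 3 and 4 for replicates 1, 2 and 3). The labels do not say that the numbers pair animals. Deviations of same-numbered arrays from their group means correlated at −0.62, −0.18 and 0.37. With 3 arrays per group, these correlations cannot show whether the numbers pair the arrays. Of 1010 values of named miRNAs, 1 passed (miR-342-3p without GLE replicate 2) and 35, in 14 miRNAs, changed sign. Of 264 values of uncalled lists, 23 passed and 13 changed sign. Those past the threshold with all arrays kept were the Dlk1-Dio3 (0.19) and Sfmbt2 (0.29) lists with the percentile over all probes, the Dlk1-Dio3 list with the labelling spike-ins (0.23), the epithelial (−0.59) and Dlk1-Dio3 (0.35) lists with no scaling, the epithelial (−0.49), miR-30 (−0.17) and Sfmbt2 (0.17) lists with normexp, the Dlk1-Dio3 (0.71) and Sfmbt2 (0.75) lists with the deposited table, the let-7 (0.034) and hepatocellular carcinoma (0.16) lists with no filter, and the epithelial (−0.67) and Dlk1-Dio3 (0.28) lists with the block. With an array left out, 9 passed: the Sfmbt2 list without GLE replicate 1, GLE replicate 3 or model replicate 1, the epithelial list without GLE replicate 2 or model replicate 3, the miR-30 and Dlk1-Dio3 lists without GLE replicate 2, and the muscle (adjusted p = 0.0471) and let-7 (adjusted p = 0.0463) lists without GLE replicate 3. The shift then ran from −0.14 to 0.69 for muscle, −1.43 to 0.032 for epithelial, −0.038 to 0.14 for let-7, −0.44 to 0.016 for miR-30, 0.042 to 0.54 for Dlk1-Dio3 and −0.019 to 0.71 for Sfmbt2 miRNAs. Blocks for slide and scan date were not run. Signal over background limited testing to 388 of 1881 miRNAs.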

Other observations

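The tests in this part were chosen after the result was seen, except the counts of miRNAs at unadjusted p and of lists over other splits of the arrays and the camera tests without GLE replicate 3, which were planned as alternatives but set against an explanation only afterwards. GLE replicate 2 held the highest values of some liver-type miRNAs: miR-122-5p was at −1.32 there and at the floor of −4.25 in both other GLE tumours, with model replicate 1 at −3.18, and miR-194-5p, which is clustered with miR-192-5p in the genome, was at −0.97 there, at −3.90 and −4.18 in GLE replicates 1 and 3 and at −2.82, −3.39 and −4.25 in model replicates 1, 2 and 3. Not all hepatocyte list members followed: of the GLE tumours, replicate 2 was lowest in miR-101a-3p (−1.81) and miR-365-3p (−2.40). The miR-200 family of epithelial cells was also highest in that tumour, with miR-200b-3p at 2.37 against 0.90 and −0.41 in GLE replicates 1 and 3 and 2.05, 1.63 and 1.06 in model replicates 1, 2 and 3. GLE replicate 1 stood apart in muscle miRNAs, with miR-1a-3p at 0.33 against −1.57 and −1.60 in the other GLE tumours and −2.39, −1.09 and −1.22 in the model tumours. miR-8110 ran from 3.12 in GLE replicate 2 to 5.68 in GLE replicate 3, and from 3.79 to 4.37 in model tumours. The erythrocyte miRNA miR-451a was at 3.36, 2.36 and 1.45 in GLE replicates 1, 2 and 3 and at 2.42, 1.98 and 3.55 in model replicates 1, 2 and 3. miR-101a-3p, miR-194-5p, miR-200b-3p, miR-365-3p and miR-8110 were named after their values were seen.

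Over the 10 ways to split the 6 arrays into 3 and 3, too few for a share under 0.05, 10 gave at least as many miRNAs past the threshold as the real split (0, highest other 0). That count was fixed in advance, since no split can give fewer than 0, so it decides nothing. At unadjusted p under 0.05, 6 of the 10 gave at least as many as the real 6 (highest other 99), 6 gave at least the real 4 lists (highest other 11), and 2 gave at least the real immune shift of 0.60 (highest other 0.78). The split of GLE replicates 1 and 3 and model replicate 3 against the rest gave the 99, the 11 and the 0.78. It was picked as the highest after the splits were seen, has 0 miRNAs past the threshold like the real split, and keeps 2 of the 3 GLE arrays together.

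For the higher immune list, the shift without GLE replicate 3 was 0.34 with the camera call kept (adjusted p = 0.00375), which under the rule set at first argued against a single tumour, but that rule was replaced after the values were seen by the exact permutation p (0.4, smallest possible 0.1), which 2 against 3 arrays cannot bring under 0.05, so a single tumour stays open, while the fibroblast shift was 0.54 with it and 0.19 without, and the miR-17-92 shift −0.23 with it and 0.045 without, so these 2 may rest on that tumour. List SDs over the GLE tumours were 0.57 (immune), 0.71 (fibroblast) and 0.52 (miR-17-92). Immune miRNAs that vary together between tumours with no treatment effect stay open, since 28 of 100 simulated data sets without a difference called the immune list. Slide row cannot be told apart from treatment, as 0 rows held both groups. GLE treatment itself also stays open, as untested beyond the comparison.

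The first component of the arrays, computed on 372 miRNAs without the immune and fibroblast members, held 61.9% of the variance. Its Pearson r with the immune list was 0.86 (exact permutation p = 0.0264, adjusted p = 0.0660 over 10 relations, not past the threshold; rho = 0.77, exact permutation p = 0.103, adjusted p = 0.206; r = 0.81 without the 2 farthest arrays), so a differing share of immune and stromal cells in the tumour piece is a candidate explanation and a hypothesis only. A differing share of all non-tumour cells together was not decided, with r = −0.11 between the immune list and the erythrocyte members (0.93 without the 2 farthest arrays) and 0.26 with the muscle list (0.12 without them). Overall signal stays open too, at r = −0.75 (exact permutation p = 0.0917, adjusted p = 0.131; rho = −0.66, exact permutation p = 0.175; r = −0.94 without the 2 farthest arrays). For the hybridisation step r was −0.024 (exact permutation p = 0.974; rho = 0.14, exact permutation p = 0.803), under the bound of 0.3 set at first as arguing against it, but that bound ignored that 6 arrays leave r wide, and r was −0.61 without the 2 farthest arrays, so this is open as well.

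Of the immune list, miR-342-3p had a mean of 1.89 in GLE and 0.69 in model tumours, and miR-142a-3p of 1.67 and 1.14; 1 member, miR-155-5p, also stands in the hepatocellular carcinoma list, and the labels name no sorting of cells. Of the other relations to the immune list, miR-126a-3p gave r = 0.89 (exact permutation p = 0.0194, adjusted p = 0.0648; rho = 0.83, exact permutation p = 0.0583), which fell to 0.10 without the 2 farthest arrays and so rests on them. The epithelial list gave r = −0.92 (exact permutation p = 0.0125, adjusted p = 0.0625; rho = −0.77, exact permutation p = 0.103; r = −0.60 without the 2 farthest arrays). The p53 list gave r = 0.87 (exact permutation p = 0.0333, adjusted p = 0.0667; rho = 0.77, exact permutation p = 0.103) and the miR-17-92 list r = −0.81 (exact permutation p = 0.0417, adjusted p = 0.0694; rho = −0.60, exact permutation p = 0.242), which came to 0.37 and 0.38 without the 2 farthest arrays.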
